A study of Rattus norvegicus with 8 samples.

How the data were processed

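Gene expression was measured in liver RNA of male Zucker diabetic fatty rats on 8 dual-colour Agilent rat arrays, 4 of lean and 4 of obese rats. Per the labels' protocols, vehicle or testosterone undecanoate (TU, 20 mg/kg, subcutaneous) was given for 4 weeks, every 3 days for 2 weeks and weekly for the next 2 weeks. RNA was isolated from 100 mg of liver with the SV Total RNA Isolation System and 0.2 µg of total RNA was labelled with the Low Input Quick Amp kit and spike-in RNA, per the labels' protocols. Vehicle RNA was labelled with Cy3 and TU RNA with Cy5 on every array, per the labels, so no array had its dyes exchanged. Per the labels, each array is a biological replicate, and whether an RNA came from 1 animal is not given in the sources used here.

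Per the file headers, the spot and local background intensities are median pixel values per channel, read with Agilent Feature Extraction 10.7.3.1. The processed intensities in the same deposited files had been background-subtracted, spatially detrended and dye-normalized by a linear and lowess step, per the file headers. The deposited log10 ratios are those of the red over the green processed signal, per the file headers. Other columns of the deposited files hold flags per spot for signal well above background, saturation, non-uniformity and controls, per the file headers. The authors' series matrix holds processed log2 ratios per probe, whose normalization is not stated in the sources used here. Their base and direction (TU over vehicle) were found by comparing them with the scanner's log10 ratio, on which their slope was 3.33 to 3.38 per array. They correlated with the log ratio of the processed signals with r from 0.998 to 1.000. With the scanner's log ratio, brought to log2 units, r was 0.702 to 0.996, and 79.3% to 85.1% of values lay within 0.01 of that ratio. With the log ratios computed here they correlated with r from 0.237 to 0.703 over all probes. Their column medians were 0.0855, 0.0666, 0.0745 and 0.0662 for lean replicates 1 to 4 and 0.0792, 0.139, 0.0632 and 0.0459 for obese replicates 1 to 4. The number of columns not mapped to a sample was 0.

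Each array file held 45018 spots, of which 1639 were controls, and 41012 distinct probes. Median signals were 39.5 to 56 in Cy3 and 56 to 68 in Cy5, over median backgrounds of 19 to 25 and 41 to 45. Between 54 and 155 spots per array were marked as non-uniform and 0 to 3 as saturated. The log ratios of the spike-in RNAs followed their known ratios with a slope of 0.865 to 0.897. The SD of the log ratios was 0.46 on obese replicate 2 and 0.11 to 0.26 on the other arrays. Gene names came from the array annotation, where the newer of 2 versions named 16815 probes, the older alone named a further 195, and 24002 had no name, for 13458 genes in all. The accession of 13137 probes differed between the versions, and a probe without a gene name was kept as a feature of its own.

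Median signals were used because the files hold no mean signals, which the plan had assumed. Signals were background-corrected with normexp (offset 50) and normalized within arrays by loess in limma 3.58.1, with R 4.3.3, and files were read with the R package data.table (version 1.17.8). Control spots and spots marked as non-uniform were left out. A probe passed the filter if it lay well above background in either channel on at least 4 of 8 arrays, and 26967 probes did. Each named gene was represented by its brightest passing probe, which left 23177 features, 9961 of them named genes. TU responses were tested with limma (lmFit and eBayes) on the log2 ratios of all 8 arrays, with a mean per genotype and the obese minus lean difference as a contrast. Obese and lean rats were compared per channel with limma after loess and Aquantile normalization, in Cy3 for vehicle and in Cy5 for TU. The Benjamini-Hochberg threshold was 0.05, and fold changes are given with the SE of the limma fit. The median SE of a lean response was 0.072 log2 units.

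Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry beside it, and adjusted over all 28 lists per comparison. A missing value was filled with the mean of its genotype for these tests, which concerned 269 features, and a list needed at least 2 measured genes. The 18 gene lists covered lipogenesis, cholesterol synthesis, fatty acid oxidation and PPAR alpha targets, triglyceride export, lipoproteins and fatty acid uptake, bile acids, glucose metabolism, and male- and female-biased liver genes. They also covered drug metabolism, steroid hormones, growth hormone and leptin signalling, acute phase and inflammation, extracellular matrix, cell cycle, oxidative stress, ER stress, the circadian clock and the mitochondrial respiratory chain. The 10 cell type lists were those of hepatocytes, Kupffer cells, sinusoidal endothelium, stellate cells, cholangiocytes, lymphocytes, neutrophils, erythroid cells, adipocytes and pancreas. Named genes followed a rule for the lean response, the obese response, their difference and the vehicle comparison. It took up to 8 higher and 8 lower passing genes of largest absolute log2 fold change with a symbol and the same sign on all 4 arrays (for the genotype comparison, with the values of the groups wholly apart). Where fewer than 5 genes passed, the 5 of smallest p were taken. To these it added up to 4 members of smallest p per gene list, and always a fixed set with Srebf1, Fasn, Acaca, Scd, Mttp, Apob, Cpt1a, Lepr, Cyp2c11, Cyp7a1 and Pck1 where measured. Some genes that the rule or a count takes in are not reported here. The rule did not cover the cell type lists or the TU comparison, so their members that it did not take elsewhere were chosen after their values were seen, and a gene that it took for 1 comparison is also given in others. Other genes outside the rule are marked in the text. The lists, the rule, the tests of the comparisons, the filter and the alternatives were chosen before the data were examined, and the closing section names the tests that were not.

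The scripts were tested on simulated data of 23177 features with 100 changed 1.5-fold and 100 changed 2-fold. At 1.5-fold 90% were recovered for the lean response, 79% for the obese response, 60% for the difference, 37% for the vehicle comparison and 65% for the TU comparison. At 2-fold the shares were 95%, 98%, 90%, 81% and 90%, in the same order. The false share of calls was 4.64%, 5.85%, 7.41%, 2.48% and 4.91%, and 0 calls had the wrong sign. The simulated noise was independent between genes and had the same SD for a gene on all 8 arrays. The real arrays spread unequally (SD of the log ratios 0.11 to 0.46). These shares therefore test the scripts and do not give the power in the real data. Alternatives were no background correction, the processed signals of the scanner software, the authors' log ratios, median centring without loess, ratios scaled between arrays, quantile-normalized channels, and a separate-channel model over all 16 channels. Further ones were no filter, a filter on both channels of all 8 arrays, the mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, array weights, a 1.5-fold minimum, the replicate number as a block, the genotype's own arrays alone, and each array left out in turn. The closing section gives their effect.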

Results

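Liver RNA of male Zucker diabetic fatty rats was compared on 8 dual-colour oligonucleotide arrays. Of these, 4 held lean rats (fa/+) and 4 held obese rats (fa/fa), whose leptin receptor is defective. On every array, liver RNA of vehicle-treated rats carried Cy3 and liver RNA of rats given testosterone undecanoate (TU), a long-acting ester of testosterone, carried Cy5. TU was injected under the skin at 20 mg/kg over 4 weeks, and the rats are labelled as 12 weeks old. Each array is labelled as 1 of 4 biological replicates of its genotype. Between 62.2% and 68.9% of probes lay well above background in Cy3 on the lean arrays, and between 58.1% and 62.1% on the obese arrays. The Cy5 shares were 53.4% to 57.4% and 50.3% to 60.5%. After filtering, 23177 features remained, of which 9961 were named genes, each represented by its brightest probe. The log2 ratios correlated across genes with a mean r of 0.407 between lean arrays, 0.289 between obese arrays and 0.224 between a lean and an obese array, although genes are not independent replicates. No array had its dyes exchanged, so a fold change within a genotype also holds any dye bias of its probe. All lean arrays were on slide 1 and all obese arrays on slide 2, each slide with its own scan, so genotype and slide cannot be told apart.

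Which liver transcripts TU changed in lean rats was asked first. Transcripts of the adult beta-globin Hbb-b1 rose 2.61-fold with TU (log2 fold change 1.39 ± 0.20 SE, n = 4 arrays, limma adjusted p = 0.0405). The embryonic globin Hbe2 rose 1.61-fold (0.68 ± 0.084, adjusted p = 0.0268). The secreted protease inhibitor precursor Ambp rose 1.69-fold (0.76 ± 0.10), the stress-responsive gene Ndrg2 1.72-fold (0.78 ± 0.077), the kinase Pim3 1.59-fold (0.67 ± 0.082) and the hormone-responsive transcription factor Klf9 1.58-fold (0.66 ± 0.087, where another probe gave 0.33). Acox2, a peroxisomal oxidase of branched fatty acids and bile acid precursors, was 2.23-fold lower (-1.16 ± 0.17, adjusted p = 0.0435). The interferon-induced membrane protein Ifitm3 was 1.70-fold lower (-0.76 ± 0.10, adjusted p = 0.0353). The endosomal factor Rin3 fell as well (-0.66 ± 0.089), as did the ceramide-1-phosphate carrier Cptp (-0.63 ± 0.066). In all, 48 of 23177 features passed, 31 higher and 17 lower with TU, and 31 of them differed at least 1.5-fold. They included 23 named genes, 15 higher and 8 lower. With median centring in place of loess the median of all genes shifted to -0.21, and 269 features passed as higher and 5215 as lower. Ndrg2 then stood at 0.35, Ambp at 0.35, Pim3 at 0.14 and Klf9 at 0.13, all without a call, while Hbe2 at 0.37, Ifitm3 at -1.30, Rin3 at -1.18 and Cptp at -1.14 kept theirs. From the scanner software's processed signals Hbe2 was at 1.11, and Ifitm3, Rin3 and Cptp lost their calls (adjusted p = 0.121, 0.0690 and 0.0648). Without a filter Hbb-b1 and Acox2 did (0.0668 and 0.0712), and with a replicate block all genes named here but Hbb-b1 and Ndrg2. None passed with ratios scaled between arrays or with trend and robust settings (limma, 3174 and 3143 features at an unadjusted p under 0.05). The genes named here each lost their call without lean replicate 2, 3 or 4 or obese replicate 4, and all but Ndrg2 without lean replicate 1. The largest adjusted p of a gene lay between 0.113 (Ndrg2) and 0.205 (Acox2 and Klf9). Without obese replicate 1 all but Ndrg2 and Cptp lost theirs, and without obese replicate 3 Ambp, Hbe2, Pim3, Klf9 and Rin3 did. The count was 6, 1, 4 and 3 without lean replicates 1 to 4, and 10, 25 and 3 without obese replicates 1, 3 and 4. It was 1047 (419 higher and 628 lower) without obese replicate 2, whose log ratios spread the most.

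Central genes of lipid, glucose and steroid biology did not pass in lean rats. Fasn, which builds fatty acids, had a log2 fold change of -1.36 ± 0.32 (adjusted p = 0.110). The elongase Elovl6 stood at -1.33 ± 0.46 (adjusted p = 0.230, another probe -0.46). The fatty acid transporter of mitochondria Cpt1a stood at 0.78 ± 0.29 (adjusted p = 0.254) and the gluconeogenic Pck1 at 0.92 ± 0.26 (adjusted p = 0.164). Values nearer 0 were found for Scd (-0.21 ± 0.30), Acaca (0.16 ± 0.25, 3 arrays), Mttp (-0.27 ± 0.12, another probe -0.093), Apob (-0.37 ± 0.18) and the leptin receptor Lepr (-0.10 ± 0.047). The male-specific Cyp2c11 stood at 0.25 ± 0.083 (adjusted p = 0.219) and the bile acid enzyme Cyp7a1 at -1.14 ± 0.59 (adjusted p = 0.412). Some of these means leaned on 1 array. On lean replicate 2 Cyp7a1 was at -3.27 (others -2.03 to 0.63) and Cpt1a at 1.81 (others 0.15 to 1.02). On lean replicate 1 Apob was at -0.98 (others -0.23 to -0.046). Srebf1 had no named probe.

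Whether whole groups of genes moved with TU in lean rats was tested with lists fixed in advance. The 34 genes of fatty acid oxidation and PPAR alpha targets lay higher than other genes (median log2 ratio 0.22, or -0.23 with median centring, camera adjusted p = 2.36e-08, adjusted p = 0.179 with an estimated correlation). Acaa2 stood at 0.39 ± 0.085, where another probe gave -0.073, and Cyp4a1 at 0.46 ± 0.11. No member passed limma over all genes (15 at an unadjusted p under 0.05), and 8 passed as higher adjusted over the list alone. Lipogenesis (24 genes) lay lower (median -0.23, camera adjusted p = 0.0411, adjusted p = 0.582 with an estimated correlation), with Fasn at -1.36 ± 0.32 and Acly at -0.90 ± 0.26. Cholesterol synthesis (25 genes) lay lower (median -0.17, camera adjusted p = 0.0201, adjusted p = 0.431 with an estimated correlation), with Mvd at -0.68 ± 0.19 and Dhcr7 at -0.56 ± 0.18. In neither list did a member pass limma over all genes or adjusted over the list alone, with 5 and 5 at an unadjusted p under 0.05. Across 20 other settings the lipogenesis call was lost in 10 and the cholesterol call in 6. Their medians ran from -0.72 to -0.18 and from -0.70 to -0.10. For 31 genes of triglyceride export, lipoproteins and fatty acid uptake the test pointed up and the mean was 0.057. The median of those genes was -0.024 (-0.34 with median centring, 0.046 with ratios scaled between arrays, camera adjusted p = 0.0201, adjusted p = 0.423 with an estimated correlation). Apoc2 of that list rose (0.48 ± 0.071, but 0.058 with median centring and 0.22 from the scanner software's processed signals, both without a call), Apoa4 was at 0.63 ± 0.10 and Apoc3 at 0.83 ± 0.16 without passing. In that list 7 were higher and 2 lower adjusted over the list alone. The cholesterol call was lost without lean replicate 1 (0.486), the lipogenesis call without lean replicate 1 (0.129) and lean replicate 2 (0.169) and the triglyceride export call without lean replicate 2 (0.0554) and lean replicate 3 (0.194) (camera adjusted p in parentheses). Without lean replicate 1 the cholesterol median was -0.10 and the triglyceride export median 0.021, and without lean replicate 2 the latter was 0.024. Apoc2 lost its call without lean replicates 1 to 4 and obese replicates 1, 3 and 4 (adjusted p up to 0.248).

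Male-biased, steroid hormone, acute phase and drug metabolism genes lay higher in lean rats as well. The 16 male-biased liver genes lay higher (median log2 ratio 0.19, or -0.30 with median centring, camera adjusted p = 0.00119, adjusted p = 0.179 with an estimated correlation). Mup4 stood at 0.46 ± 0.11 and Mup5 at 0.37 ± 0.080. No male-biased gene passed over all genes (7 at an unadjusted p under 0.05), and 3 were higher adjusted over the list alone. Among 23 genes of steroid hormone metabolism and receptors (median log2 ratio 0.035, or -0.36 with median centring, camera adjusted p = 0.00138, adjusted p = 0.256 with an estimated correlation), Ugt2b, which conjugates androgens, rose (0.50 ± 0.062), and so did Hsd17b13 (0.43 ± 0.060, or -0.074 with median centring). Ugt2b was at 0.051 with median centring and 0.30 from the scanner software's processed signals, both without a call. The rest did not pass, among them the testosterone-reducing enzyme Srd5a1 (-0.81 ± 0.17, adjusted p = 0.0989). Adjusted over the list alone, 6 were higher and 1 lower. The 35 acute phase and inflammation genes lay higher (median log2 ratio 0.11, or -0.20 with median centring, camera adjusted p = 0.00322, adjusted p = 0.179 with an estimated correlation). Serpina3n of that list rose (0.53 ± 0.075, but 0.11 with median centring and 0.29 from the scanner software's processed signals, both without a call), while Orm1 at 0.73 ± 0.16 and Icam1 at -0.42 ± 0.092 did not pass. Adjusted over that list alone, 3 were higher and 1 lower. Drug metabolism genes (22) lay higher (median log2 ratio 0.094, or -0.23 with median centring, camera adjusted p = 0.0201, adjusted p = 0.256 with an estimated correlation). None was past the threshold over all genes (7 at an unadjusted p under 0.05), 1 passed adjusted over the list alone, and Aldh1a1 stood at 0.48 ± 0.082. Calls of single genes were lost for Ugt2b without lean replicates 1 to 4 and obese replicates 1 and 4 (to 0.200), Hsd17b13 without lean replicates 1 to 4 and obese replicates 1, 3 and 4 (to 0.200) and Serpina3n without lean replicates 1 to 4 and obese replicates 1, 3 and 4 (to 0.240), with the adjusted p rising to the value in parentheses. The list calls held without any 1 array, but some medians moved over 1.5 times. This was so without lean replicate 1 for acute phase (0.056) and steroid hormone genes (0.066), without lean replicate 2 for drug metabolism (0.025), and without lean replicates 3 (0.072) and 4 (0.022) for steroid hormone genes.

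Markers of the cells of the liver gave 2 further lean calls. Members of the cell type lists named here and below were chosen after their values were seen, except where the rule for named genes took them. All 10 Kupffer cell and macrophage markers lay below 0 (median -0.16, camera adjusted p = 0.00616, adjusted p = 0.256 with an estimated correlation). Among them, Cd68 stood at -0.42 ± 0.081 (adjusted p = 0.0810) and Adgre1 at -0.33 ± 0.066. None passed over all genes, and 2 were lower adjusted over the list alone and at an unadjusted p under 0.05. Without lean replicate 4 the call was lost (camera adjusted p = 0.0545), and without lean replicate 1 the median was -0.26. Hepatocyte markers (9 genes) lay higher (median log2 ratio 0.29, or -0.13 with median centring, camera adjusted p = 0.00138, adjusted p = 0.340 with an estimated correlation). Ambp rose, a call that was lost without lean replicates 1 to 4 and obese replicates 1, 3 and 4 (adjusted p up to 0.200). Ttr at 0.58 ± 0.16 and Fgb at 0.52 ± 0.21 did not pass, and adjusted over the list alone 3 were higher and 1 lower. Erythroid markers (3 genes) had a median of 0.79 and did not pass (camera adjusted p = 0.0501). Alas2 stood at 0.98 ± 0.27 and Hbb at 0.79 ± 0.40, beside the rise of Hbb-b1 outside the list. No camera call was made in lean rats for female-biased genes (median -0.17, adjusted p = 0.0861), glucose metabolism (0.083, 0.0861) or the mitochondrial respiratory chain (0.041, 0.0892). None was made for oxidative stress and NRF2 targets (0.035, 0.110) or growth hormone and leptin signalling (0.014, 0.114), which shares Serpina3n with the acute phase list. The same held for stellate cells (-0.20, 0.146), adipocytes (0.041, 0.162), extracellular matrix and stellate activation (-0.13, 0.174), ER stress and amino acid response (-0.11, 0.250), lymphocytes (-0.095, 0.290) and neutrophils (0.12, 0.415, 2 genes). It also held for pancreas (-0.00088, 0.712), circadian clock (-0.0016, 0.712), cell cycle (-0.035, 0.740), cholangiocytes (-0.021, 0.887), bile acid synthesis and transport (0.0065, 0.887) and sinusoidal endothelium (-0.064, 0.891). The test pointed up against the median for cell cycle and pancreas, and for bile acids the mean was -0.039. No member of these 17 uncalled lists passed over all genes, except Serpina3n.

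**Figure D1:**
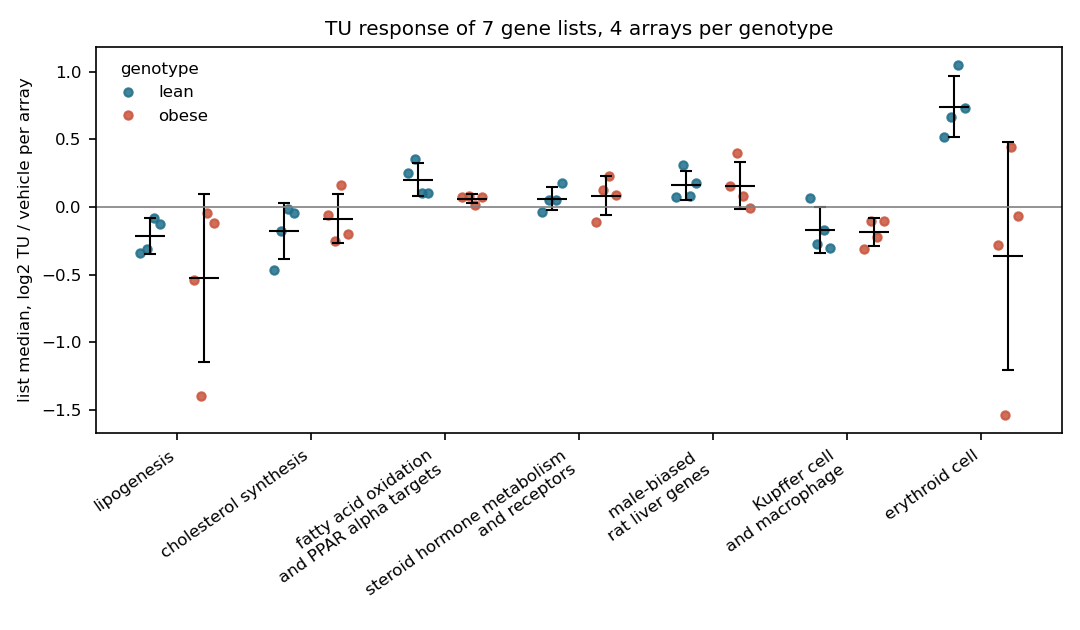
Median log2 ratio (TU over vehicle) of the genes of 7 lists on each array, with points for single arrays and bars for the mean ± SD of the 4 lean (blue) and 4 obese (red) arrays. Lipogenesis stood at -0.22 ± 0.13 in lean and -0.52 ± 0.62 in obese rats, erythroid markers at 0.74 ± 0.23 and -0.36 ± 0.84, and fatty acid oxidation and PPAR alpha targets at 0.20 ± 0.12 and 0.061 ± 0.031, where the lean direction of this last list turned to a median of -0.23 with median centring.

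**Figure D2:**
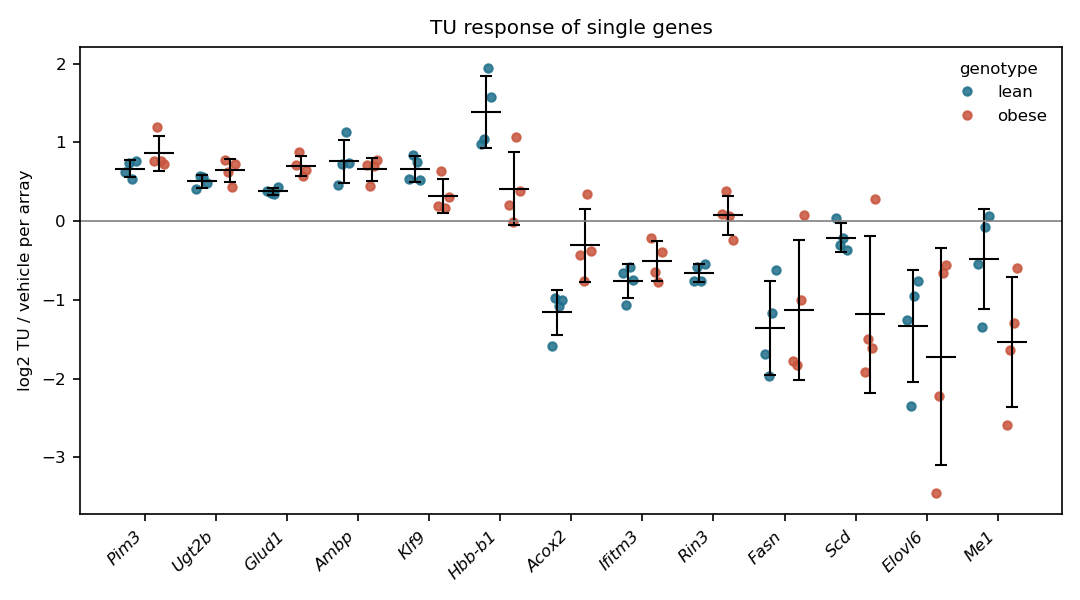
Log2 ratio (TU over vehicle) of named genes on each array, with points for single arrays and bars for the mean ± SD of the 4 lean (blue) and 4 obese (red) arrays. Pim3 stood at 0.67 ± 0.11 in lean and 0.86 ± 0.23 in obese rats, Glud1 at 0.38 ± 0.041 and 0.70 ± 0.13, and Fasn at -1.36 ± 0.60 and -1.13 ± 0.89.

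Which liver transcripts TU changed in obese rats, which carry the defective leptin receptor, was asked next. Glud1, the mitochondrial glutamate dehydrogenase, rose 1.63-fold (0.70 ± 0.054, n = 4 arrays, limma adjusted p = 0.0123). The kinase Pim3 rose 1.82-fold (0.86 ± 0.082, adjusted p = 0.0269) and Ugt2b rose 1.56-fold (0.64 ± 0.062, adjusted p = 0.0269). These 3 of 23177 features were all that passed, and all 3 were also called in lean rats, where Glud1 stood at 0.38 ± 0.054. A further probe of Ugt2b gave 0.41 in obese and 0.34 in lean rats. The other probes of Glud1 gave -0.17 and -0.19 in obese and -0.14 and -0.076 in lean rats, and Pim3 had no second probe. At an unadjusted p under 0.05 there were 2952 features, where chance gives 1159. Other ways of processing split the calls differently. There were 161 higher and 57 lower from the scanner software's processed signals, 148 and 53 from the authors' log ratios, and 61 and 20 without background correction. With median centring Glud1 was at 1.16, Pim3 at 1.04 and Ugt2b at 1.15, and with ratios scaled between arrays at 1.63, 2.10 and 1.33, all without a call. The mean of its probes put Glud1 at 0.11 (adjusted p = 0.529), and no gene passed with such means, trend and robust settings, a replicate block or obese arrays alone (limma, 2893, 2499, 3139 and 1544 features at an unadjusted p under 0.05). Glud1 and Ugt2b lost their calls from the processed signals (0.0516 and 0.0656). Each of the 3 calls was lost without some single arrays, lean arrays included, since both genotypes shared the estimate of the spread. Glud1 was lost without lean replicates 1 to 4 (adjusted p = 0.0679, 0.0671, 0.0674 and 0.0599) and obese replicate 1 (0.174). Without lean replicates 1 to 4 Pim3 and Ugt2b were lost as well (0.118, 0.108, 0.107 and 0.111 for both), as without obese replicate 1 (0.174 for both). Pim3 was also lost without obese replicates 3 (0.146) and 4 (0.0666), and Ugt2b without obese replicates 2 (0.0898) and 4 (0.115). Without lean replicate 1, 2, 3 or 4 or obese replicate 1 no feature passed, with 2645, 2580, 2406, 2573 and 2071 at an unadjusted p under 0.05.

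Lipogenic genes showed the clearest group response to TU in obese rats. The lipogenesis list lay lower (median -0.59, 23 of 24 genes below 0, camera adjusted p = 2.95e-11, adjusted p = 0.579 with an estimated correlation). Without obese replicate 2, which alone had a list median under -1, the median was -0.28 with the call kept (camera adjusted p = 1.55e-09). Its members included Elovl6 (-1.72 ± 0.46), Me1, which supplies NADPH (-1.53 ± 0.31), the desaturases Scd (-1.18 ± 0.30) and Scd2 (-1.15 ± 0.28), and Fasn (-1.13 ± 0.32). Other probes gave -0.063 and -0.0012 for Scd2, -1.22 for Elovl6, -1.0 for Me1 and -1.11 for Fasn. None of the members passed limma over all genes (16 at an unadjusted p under 0.05, and an adjusted p of 0.211 for Me1). Adjusted over the list alone, 10 were lower. Kupffer cell and macrophage markers lay below 0 in 10 of 10 genes (median -0.17, camera adjusted p = 0.00199, adjusted p = 0.579 with an estimated correlation). Of these, Cd68 stood at -0.45 ± 0.081 and Clec4f at -0.40 ± 0.19. The array medians of the Kupffer list averaged -0.19 in obese and -0.17 in lean rats, which a dye bias shared by both slides would also give. No Kupffer marker passed over all genes (3 at an unadjusted p under 0.05), and 2 were lower adjusted over the list alone. Steroid hormone genes lay higher (median 0.082, camera adjusted p = 0.00199, adjusted p = 0.579 with an estimated correlation). Ugt2b rose, while the cortisone-reducing enzyme Hsd11b1 at 0.70 ± 0.11 (another probe 1.09) and Srd5a1 at -0.77 ± 0.17 did not pass. Among all steroid hormone genes 5 were higher and 1 lower adjusted over the list alone. Without obese replicate 3 the Kupffer and steroid hormone calls were lost (camera adjusted p = 0.100 and 0.106), and the steroid hormone median was 0.046 without that array and 0.15 without obese replicate 1. Across 20 other settings the Kupffer call was lost in 5 and the steroid hormone call in 7. Their medians ran from -0.56 to -0.041 and from 0.046 to 0.45. Fatty acid oxidation and PPAR alpha targets (median 0.086, camera adjusted p = 0.0696), male-biased genes (0.18, 0.0890), ER stress (-0.12, 0.0930) and erythroid markers (-0.29, 0.290) did not pass. For the other 21 lists the camera adjusted p was 0.301 or more. Among these, the median went against the test for hepatocytes (-0.11), glucose metabolism (-0.022), pancreas (-0.0066) and lymphocytes (0.0083). The mean did so for cholesterol synthesis (0.023), growth hormone and leptin signalling (-0.0013) and lymphocytes (0.00057). Of the genes chosen in advance, Cpt1a stood at 0.091 ± 0.29, Acaca at -0.33 ± 0.22, Mttp at 0.0064 ± 0.12 (another probe -0.45), Apob at -0.16 ± 0.18 (others 0.086, -0.33, 0.091 and -0.28), and Lepr at -0.018 ± 0.047. Pck1 stood at -0.067 ± 0.26, Cyp2c11 at -0.21 ± 0.083 and Cyp7a1 at 0.47 ± 0.68 on 3 arrays. On obese replicate 2 Acaca was at -1.35, against -0.019 to 0.074 on the other obese arrays. Cpt1a was at 0.80 on obese replicate 1, against -0.54 to 0.22 on the others.

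Whether the response to TU differed between obese and lean rats, as the series title's leptin dependence asks, was tested as the difference of the responses. Of 23177 features 1 passed (n = 4 against 4 arrays, limma), and none did without lean replicate 1, 2, 3 or 4 or obese replicate 1 or 4. There were 1188, 1253, 1583 and 1800 features at an unadjusted p under 0.05 without lean replicates 1 to 4, and 1839 and 1681 without obese replicates 1 and 4. Without obese replicate 2, 3 features passed. Next by p, though not passing, came the fetal plasma protein Afp (0.84 ± 0.12, adjusted p = 0.310), Cptp (0.60 ± 0.093, 0.425), the olfactory receptor gene Or4f7c (-0.57 ± 0.10, 0.509) and Rin3 (0.73 ± 0.13, 0.509). Lipogenic genes gave differences of 0.23 ± 0.45 for Fasn (adjusted p = 0.873), -0.97 ± 0.42 for Scd (0.628), -1.18 ± 0.39 for Scd2 (0.615) and -1.05 ± 0.44 for Me1 (0.626). Other probes gave 0.52 and -0.049 for Scd2, 0.42 for Fasn and -0.89 for Me1. Cyp2c11 differed by -0.45 ± 0.12 (adjusted p = 0.615), Cpt1a by -0.69 ± 0.41 (0.681), Pck1 by -0.98 ± 0.37 (0.620) and Cyp7a1 by 1.61 ± 0.90 (0.671). Acaca, Mttp, Apob and Lepr differed by -0.49, 0.28, 0.21 and 0.080, none passing, where another probe of Mttp gave -0.36 and those of Apob 0.50, 0.16, 0.32 and 0.20. At an unadjusted p under 0.05 there were 1840 features, where chance gives 1159.

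At the level of gene groups, 6 lists responded differently in obese and lean rats, and in none did a member pass limma over all genes. The 3 erythroid markers had lower ratios in obese rats (median difference -1.26, camera adjusted p = 0.00485, adjusted p = 0.622 with an estimated correlation), with Alas2 at -1.26 ± 0.38 and Slc4a1 at -0.36 ± 0.18. For this list, without obese replicate 2 the median was -0.84 with the call kept. Across 20 other settings its median ran from -1.515 to -0.11, and the call was lost in 3. Lipogenesis had lower ratios of TU over vehicle in obese rats (median difference -0.26, or 0.19 with median centring, 19 of 24 genes below 0, camera adjusted p = 0.00485, adjusted p = 0.681 with an estimated correlation). Its median without obese replicate 2 was -0.081, and the call was lost (camera adjusted p = 0.140). Fatty acid oxidation and PPAR alpha targets had lower ratios in obese rats (median -0.10, or 0.52 with median centring, camera adjusted p = 0.00993, adjusted p = 0.681 with an estimated correlation). The lipoprotein lipase inhibitor Angptl4 of that list stood at -1.28 ± 0.43. The fatty acid oxidation call was lost without lean replicate 2 (median -0.026, camera adjusted p = 0.218), and the median was -0.15, -0.17 and -0.17 without lean replicates 1, 3 and 4. Stellate cell markers had higher ratios in obese rats in 8 of 8 genes (median 0.24, camera adjusted p = 0.0300, adjusted p = 0.622 with an estimated correlation). Col1a1 stood at 1.39 ± 0.72 and Reln at 0.49 ± 0.14. The extracellular matrix list, which shares Pdgfrb, Col1a1 and Col3a1 with the stellate list, had higher ratios too (median 0.19, or -0.044 with ratios scaled between arrays, camera adjusted p = 0.0418, adjusted p = 0.681 with an estimated correlation). Oxidative stress and NRF2 targets had lower ratios in obese rats (median -0.11, or 0.44 with median centring, camera adjusted p = 0.0413, adjusted p = 0.567 with an estimated correlation). They did so by fry as well (adjusted p = 0.0293), while the fry results of the other list calls are not given here. The stellate call was lost without lean replicate 3 (0.0502), obese replicate 2 (0.159) and obese replicate 4 (0.0625), the oxidative stress call without lean replicate 3 (0.0954), obese replicate 1 (0.0725) and obese replicate 3 (0.0605), and the extracellular matrix call without lean replicate 2 (0.102), lean replicate 3 (0.0581), lean replicate 4 (0.0510), obese replicate 1 (0.0619), obese replicate 2 (0.227) and obese replicate 4 (0.0556) (camera adjusted p in parentheses). Without obese replicate 2 the stellate median was 0.13 and the extracellular matrix median 0.089. Adjusted over the list alone 2 erythroid genes were lower, Hbb and Alas2, and no gene of the other 5 lists passed. At an unadjusted p under 0.05 there were 2 erythroid, 3 lipogenesis, 5 fatty acid oxidation, 1 stellate, 2 oxidative stress and 3 extracellular matrix genes. The smallest camera adjusted p among the lists not called were 0.0660 for acute phase (median -0.066), 0.0719 for cholesterol synthesis (0.12) and 0.0934 for hepatocytes (-0.27). Kupffer markers (0.0041, 0.873) and steroid hormone genes (0.042, 0.873) had medians above 0 with the test pointing down.

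Whether genes responded alike in both genotypes was described across genes. The lean and obese mean log2 ratios correlated with a Pearson r of 0.369 and a Spearman rho of 0.297 across 23177 genes, which are not independent replicates. With median centring r was -0.117. Without obese replicate 2 it was 0.463. Of the 48 features called in lean rats, 45 had the same sign in obese rats. Glud1, Pim3 and Ugt2b were called in both, where the shared estimate of the spread favours the same genes. A dye bias common to all arrays would raise these values.

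How the livers of obese and lean rats differed without TU was asked from the Cy3 channel. The clock output factor Dbp was 17.4-fold higher in obese rats under vehicle (log2 fold change 4.12 ± 0.28, n = 4 against 4 arrays, limma adjusted p = 0.000346). Fasn was 6.55-fold higher (2.71 ± 0.33, adjusted p = 0.00282). The lipid droplet lipase gene Pnpla5 was 9.81-fold (3.29 ± 0.38) higher, the fasting hormone Fgf21 7.66-fold (2.94 ± 0.47) and the lysolipid transporter Mfsd2a 6.95-fold (2.80 ± 0.18). The steroid hydroxylase Cyp17a1 was 6.23-fold higher (2.64 ± 0.15) and the sulfotransferase Sult2a2 5.77-fold (2.53 ± 0.33). The sterol exporter Abcg5 was lower (-3.42 ± 0.32, adjusted p = 0.00112). The carboxylesterases Ces1dl1 and Ces1d were 6.53-fold lower (-2.71 ± 0.11) and 6.09-fold lower (-2.61 ± 0.22). The trefoil factor Tff1 was 7.41-fold lower (-2.89 ± 0.19) and the receptor Gfra1 6.18-fold lower (-2.63 ± 0.23). The desaturase Scd was 4.02-fold higher (2.01 ± 0.29) and Elovl6 4.79-fold (2.26 ± 0.53). The beta-globin Hbb-b1 was 2.19-fold higher (1.13 ± 0.22). Cpt1a (1.53 ± 0.35) and Apob (0.65 ± 0.17) were higher as well. Other probes gave 1.36 for Fasn, 1.73 for Mfsd2a, -1.02 for Gfra1, 1.54 for Elovl6, and 0.53, 0.93, 0.18 and 0.93 for Apob. Over the 415 called genes with other probes, the brightest of these gave a median of 0.342 of the reported log2 difference. From the scanner software's processed signals Sult2a2 was at 5.27, Abcg5 at -5.35, Tff1 at -5.07 and Ces1dl1 at -5.55. With single arrays left out in turn, calls were lost (with the adjusted p rising to the value in parentheses) for Elovl6 without lean replicates 1 to 4 and obese replicate 4 (to 0.0891), Hbb-b1 without lean replicate 4 (to 0.0523), Cpt1a without lean replicates 1 to 4 and obese replicates 3 and 4 (to 0.0823) and Apob without lean replicates 2, 3 and 4 and obese replicates 3 and 4 (to 0.118). No difference passed for Mttp (-1.58 ± 0.67, adjusted p = 0.152, where another probe gave 0.43), Cyp2c11 (-0.50 ± 0.17), Acaca (0.47 ± 0.32), Lepr (0.058 ± 0.088), Pck1 (-0.29 ± 1.20, where another probe gave 0.21) or Cyp7a1 (-0.068 ± 0.47). In all, 3423 features (14.8%) passed, 1708 higher and 1715 lower in obese rats, and 1557 differed at least 1.5-fold. The count was 1527, 1574, 1465 and 1518 without lean replicates 1 to 4. Because genotype and slide cannot be told apart, each of these values holds any difference between the slides.

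Lipid metabolism set the obese liver apart at the level of lists too. Lipogenesis was higher in obese rats (median log2 difference 1.09, camera adjusted p = 3.23e-05, adjusted p = 0.333 with an estimated correlation). In that list 10 genes passed as higher, among them Fasn, Elovl6 and Scd, with 17 higher and 1 lower adjusted over the list alone. Fatty acid oxidation and PPAR alpha targets were higher (median log2 difference 0.39, camera adjusted p = 3.23e-05, adjusted p = 0.0535 with an estimated correlation). In this list 9 genes were higher, such as Acaa1b (1.59 ± 0.12), Eci1 (1.43 ± 0.12) and Hadhb (1.41 ± 0.13). Chosen after their values were seen, the lower genes of that list were the thioesterase Acot3 (-0.68 ± 0.11) and the dehydrogenase Acadm (-0.61 ± 0.12). Adjusted over the list alone, 12 were higher and 2 lower. Both lists kept their calls without any 1 array. Cholesterol synthesis was lower (median log2 difference -0.32, camera adjusted p = 0.00770, adjusted p = 0.299 with an estimated correlation). There, 7 genes were lower, such as Idi1 (-2.15 ± 0.26, where another probe gave -1.46) and Sqle (-1.16 ± 0.088). A single gene was higher. The counts were the same adjusted over the list alone. Triglyceride export, lipoproteins and fatty acid uptake lay higher (median log2 difference 0.24, camera adjusted p = 0.0409, adjusted p = 0.299 with an estimated correlation). Of its genes 6 were higher, such as Cd36 (1.70 ± 0.24) and Fabp2 (2.03 ± 0.16), and Ces1d was lower, with 8 higher and 1 lower adjusted over the list alone. The mitochondrial respiratory chain lay higher (median log2 difference 0.24, camera adjusted p = 0.0409, adjusted p = 0.299 with an estimated correlation). Of these genes 9 were higher, such as Ndufv2 (1.03 ± 0.080) and Uqcrfs1 (0.86 ± 0.10), and Sdhc was lower (-1.06 ± 0.083), with 11 higher and 2 lower adjusted over the list alone. With the scanner software's processed signals Cd36 was at 2.55 and Sdhc at -0.50, the latter without a call. The cholesterol call was lost without obese replicate 3 (0.0749), the triglyceride export call without lean replicate 3 (0.0612), obese replicate 2 (0.123) and obese replicate 3 (0.0749) and the mitochondrial call without lean replicate 3 (0.0612), obese replicate 3 (0.0861) and obese replicate 4 (0.0955) (camera adjusted p in parentheses). The cholesterol median was -0.19 without obese replicate 3, and the mitochondrial median was 0.43 without obese replicate 1 and 0.15 without obese replicate 4. Among the named genes, calls were lost for Elovl6 without lean replicates 1 to 4 and obese replicate 4 (to 0.0891) and Acadm without lean replicate 1 (to 0.0501), with the adjusted p rising to the value in parentheses.

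Sex-biased genes differed between obese and lean males under vehicle. Male-biased genes were lower (median log2 difference -0.26, camera adjusted p = 0.0459, adjusted p = 0.299 with an estimated correlation). Cyp3a2 was 30.4-fold lower (-4.93 ± 0.67), with Cyp3a18 at -2.50 ± 0.40, the pheromone carrier Obp3 at -1.30 ± 0.17 and Hao2 at -1.43 ± 0.29. These 4 genes passed, also adjusted over the list alone. Female-biased genes were higher (median log2 difference 0.88, camera adjusted p = 0.0285, adjusted p = 0.387 with an estimated correlation). Among the 5 higher genes were Cyp2c12 (1.75 ± 0.15), the prolactin receptor Prlr (1.66 ± 0.20), Srd5a1 (1.27 ± 0.17, where another probe gave 0.85) and Sult2a2. Stac3, an adaptor of muscle calcium channels, was lower (-2.04 ± 0.18), as was the trefoil factor Tff3 (-0.88 ± 0.15, chosen after its value was seen, where another probe gave -0.57), and adjusted over the list alone 7 were higher and 2 lower. In the scanner software's processed signals Cyp2c12 was at 2.66 and Prlr at 2.80. Calls were lost without lean replicate 1 (0.0674), lean replicate 3 (0.0612), obese replicate 1 (0.159), obese replicate 2 (0.0694) and obese replicate 4 (0.0885) for male-biased genes, and obese replicate 2 (0.120) and obese replicate 3 (0.0923) for female-biased genes (camera adjusted p in parentheses). The male-biased median was -0.15 without lean replicate 1, -0.16 without lean replicate 2 and -0.070 without obese replicate 1, and the female-biased median was 1.38 without obese replicate 1. Of the single genes, the call was lost for Hao2 without lean replicates 1 to 4 (to 0.0626), with the adjusted p rising to the value in parentheses.

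Clock, cell cycle and cell type lists differed under vehicle as well. The circadian clock list was higher (median log2 difference 0.27, camera adjusted p = 0.0405, adjusted p = 0.299 with an estimated correlation). In it 4 genes were higher, among them Dbp and Per3, whose lean vehicle signal lay below background (at least 1.20-fold higher). The 2 lower genes were Bmal1 (-0.59 ± 0.15) and the repressor Cry1 (-0.72 ± 0.19, chosen after its value was seen). Adjusted over the clock list alone 7 were higher and 2 lower. Cell cycle genes were higher (median log2 difference 0.26, camera adjusted p = 0.0285, adjusted p = 0.395 with an estimated correlation). Of them 7 were higher, such as the cyclin Ccne1 (0.96 ± 0.12), and 2 were lower, Pcna (-2.48 ± 0.28, where another probe gave 0.39) and the inhibitor Cdkn1a (-0.55 ± 0.15, where another probe gave -0.080). Ccne1 was at 1.46 without background correction, at 2.02 with processed signals, and Pcna at -3.96 with the latter and -1.05 as the mean of its probes. Adjusted over the cell cycle list alone the counts were the same. Across 18 other settings the cell cycle median ran from 0.21 to 0.64, and the call was lost in 4. Lymphocyte markers were lower (median log2 difference -0.22, camera adjusted p = 0.0409, adjusted p = 0.387 with an estimated correlation). There, Cd3d (-0.82 ± 0.13) and Cd3g (-0.31 ± 0.073) were past the threshold, also adjusted over the list alone. Sinusoidal endothelium markers were lower too (median log2 difference -0.27, camera adjusted p = 0.0409, adjusted p = 0.299 with an estimated correlation), with Tek (-0.70 ± 0.075) past it in both ways. The endothelium median ran from -0.66 to -0.20 across the 18 settings. Calls were lost without obese replicate 1 (0.0610), obese replicate 3 (0.0749) and obese replicate 4 (0.0541) for the clock, and obese replicate 3 (0.0749) and obese replicate 4 (0.0541) for the cell cycle (camera adjusted p in parentheses). They were also lost without lean replicate 1 (0.0674), obese replicate 3 (0.0923) and obese replicate 4 (0.0805) for lymphocytes, and lean replicate 3 (0.0561), obese replicate 3 (0.101) and obese replicate 4 (0.0955) for endothelium. Single genes lost their calls in this way too, with the adjusted p rising to the value in parentheses: Bmal1 without lean replicates 1 to 4 and obese replicate 4 (to 0.0986), Per3 without lean replicates 1 to 4 and obese replicates 3 and 4 (to 0.116), Cry1 without lean replicates 1 to 4 and obese replicates 2, 3 and 4 (to 0.115), Cdkn1a without lean replicates 1, 3 and 4 and obese replicates 1, 3 and 4 (to 0.124) and Cd3g without lean replicates 1 to 4 and obese replicates 3 and 4 (to 0.0906). Erythroid markers (0.91, 0.227) and Kupffer markers (0.071 with the test pointing down, 0.944) were not called under vehicle.

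**Figure D3:**
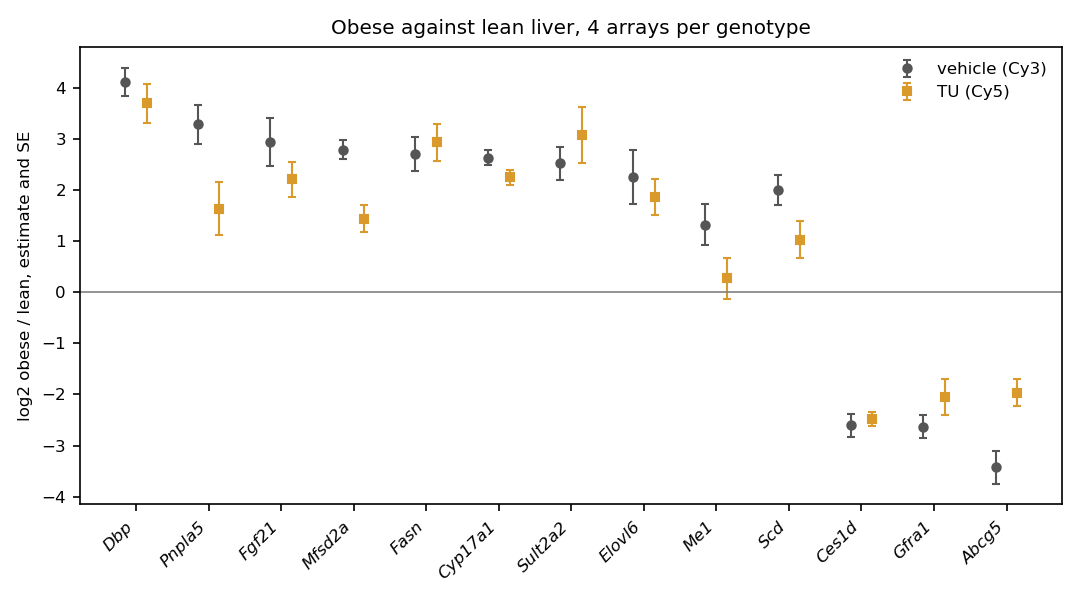
Log2 difference between obese and lean rats (estimate ± SE, n = 4 against 4 arrays) of named genes under vehicle (Cy3) and under TU (Cy5). Dbp stood at 4.12 ± 0.28 and 3.71 ± 0.38, Fasn at 2.71 ± 0.33 and 2.94 ± 0.36, and Scd at 2.01 ± 0.29 and 1.03 ± 0.36.

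How obese and lean livers differed under TU was asked from the Cy5 channel. Fasn was higher in obese rats (2.94 ± 0.36, n = 4 against 4 arrays, limma adjusted p = 0.00176), as were Dbp (3.71 ± 0.38), Cyp17a1 (2.25 ± 0.15) and Sult2a2 (3.08 ± 0.55). Abcg5 (-1.96 ± 0.27), Cyp3a2 (-4.73 ± 0.78) and Ces1d (-2.48 ± 0.14) were lower, and so was Cyp2c11 (-0.95 ± 0.089, adjusted p = 0.000717). Scd (1.03 ± 0.36, adjusted p = 0.0803) and Pnpla5 (1.64 ± 0.53, 0.0614), which passed under vehicle, did not pass under TU. Me1 passed neither under TU (0.28 ± 0.40, 0.674) nor under vehicle (1.33, where another probe gave 2.30). In all, 4755 features (20.5%) passed, 2666 higher and 2089 lower. The brightest other probe of 590 called genes gave a median of 0.342 of the reported log2 difference. The count was 3009, 3043 and 7282 without lean replicates 1 and 4 and obese replicate 1. Lipogenesis (median 0.70, camera adjusted p = 0.000111, adjusted p = 0.445 with an estimated correlation) was higher. In that list 12 genes were up and Pparg was down (-0.29 ± 0.064), with 15 higher and 1 lower adjusted over the list alone. Female-biased genes (median 1.00, camera adjusted p = 0.000530, adjusted p = 0.452 with an estimated correlation) were higher. Among these 7 were up and 2 down, Stac3 (-2.77 ± 0.29) and Tff3 (-0.30 ± 0.086), as also adjusted over the list alone. Fatty acid oxidation and PPAR alpha targets (median 0.33, camera adjusted p = 0.00659, adjusted p = 0.445 with an estimated correlation) were higher. The 11 genes up included Fgf21 (2.21 ± 0.34), and Acot3 (-0.66 ± 0.15) and Acadm (-0.66 ± 0.15) were down, with 15 higher and 2 lower adjusted over the list alone. Cell cycle genes (median 0.17, camera adjusted p = 0.00852, adjusted p = 0.445 with an estimated correlation) were higher. Across 18 other settings their median ran from 0.14 to 0.81, and the call was lost in 3, among them the replicate block. The 8 genes up included Cdk1 (1.33 ± 0.23), and Pcna (-2.26 ± 0.35) and Cdkn1a (-1.02 ± 0.16) were down, with 11 higher and 2 lower adjusted over the list alone. Male-biased genes (median -0.35, camera adjusted p = 0.00659, adjusted p = 0.312 with an estimated correlation) were lower with 5 genes past the threshold. Their median was -0.11 without obese replicate 1. Drug metabolism (median -0.21, camera adjusted p = 0.0142, adjusted p = 0.312 with an estimated correlation) was lower with 6 genes past it, such as the nuclear receptor Nr1i3 (-1.34 ± 0.22). Sinusoidal endothelium (median -0.25, camera adjusted p = 0.00659, adjusted p = 0.445 with an estimated correlation) was lower with 3, among them Tek (-0.99 ± 0.080). The endothelium median ran from -0.75 to -0.20 across the 18 settings. The male-biased, drug metabolism and endothelium lists kept those counts adjusted over the list alone. Adipocyte markers (median -0.19, camera adjusted p = 0.0293, adjusted p = 0.508 with an estimated correlation) were lower, although the median was 0.031 with the scanner software's processed signals. Cfd (-0.96 ± 0.053) and Cidea (-0.42 ± 0.11) were down and Fabp4 up (0.61 ± 0.11), also adjusted over the list alone. The adipocyte call was lost without lean replicate 2 (0.0555), obese replicate 1 (0.0929), obese replicate 3 (0.0775) and obese replicate 4 (0.0515) (camera adjusted p in parentheses). The rule for named genes did not cover this comparison, and those it did not name elsewhere, such as Pparg, Cidea, Cfd and Fabp4, were chosen after their values were seen. Without single arrays calls were lost for Pparg without lean replicates 1 and 4 (to 0.0514), Tff3 without lean replicates 1 to 4 and obese replicates 3 and 4 (to 0.117), Acot3 without obese replicate 4 (to 0.0525), Acadm without lean replicate 2 (to 0.0506) and Cidea without lean replicates 1 to 4 and obese replicates 2 and 3 (to 0.0876), with the adjusted p rising to the value in parentheses.

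Whether TU moved obese livers away from or along their starting difference was asked across genes. The obese minus lean difference under vehicle and the obese response to TU share the obese vehicle RNA, which pulls their covariance below 0 without any effect of TU. With all obese arrays in both, the covariance was -0.0269 (r = -0.369). Simulated data without any effect gave a mean covariance of -0.00714 and a mean r of -0.305 over 100 draws. The simulation gave a gene the same spread in both genotypes. Real Cy3 values agreed less between obese arrays (lowest r 0.938) than between lean arrays (0.986). The pull can thus be stronger than simulated, and the gap between the 2 covariances does not show an effect of TU. With 2 obese arrays used for the difference and the other 2 for the response, the covariance averaged -0.0151 over the 6 divisions, from -0.0258 to -0.00814, and r averaged -0.169. Among genes that differed at least 2-fold, a mean of 64.3% responded against their starting difference (57.9% to 68.2%). All obese arrays share a slide with vehicle in Cy3, and a Cy3 bias of probes on that slide would pull these values the same way. Dividing the arrays does not remove it, so such a bias and an effect of TU cannot be told apart here. Without obese replicate 2 the mean covariance was -0.00603, and without obese replicate 3 it was -0.0233. The lean response set against the same kind of difference gave a mean covariance of -0.00646 (-0.0110 to -0.00268). Genes are not independent replicates, so no p-value was attached to these values. As examples, Dbp, Fasn and Scd, all higher in obese rats under vehicle, had obese responses to TU of -0.53 ± 0.26, -1.13 ± 0.32 and -1.18 ± 0.30, none of which passed. These responses share the obese vehicle RNA with the difference. Fasn was lower with TU in lean rats too (-1.36). Cpt1a, also higher in obese rats under vehicle (1.53), ranged from -0.54 to 0.80 on the obese arrays.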

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

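The tests of dye bias, of feeding state and of both scores within a genotype were chosen only after the result was seen, while the tests that regroup the arrays and the test of clock phase were written before. In 7 of 139 groups of 4 arrays 1 array lay far from the other 3 by Dixon's criterion, and chance marks about 1 in 20 groups, here 6.95, and 6 of the 7 are given. For obese replicate 2 the correlation of spike-in ratios with their known values was 0.977, against 0.993 to 0.995 on the other obese arrays. That array also stood apart for Acaca, at -1.35 against -0.019 to 0.074, and for Pim3, at 1.20 against 0.72 to 0.77. On obese replicate 3 the median of fatty acid oxidation and PPAR alpha targets was 0.015 against 0.071 to 0.082. On obese replicate 4 the share of probes well above background in Cy3 was 58.1%, against 61.5% to 62.1%. On lean replicate 1 Acox2 was at -1.59, against -1.07 to -0.97 on the other lean arrays.

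Other results stood out because the response to TU differed between obese and lean rats by a test of the difference itself. These were the medians of 6 lists by camera, erythroid markers at -1.26, lipogenesis at -0.26, stellate cells at 0.24, extracellular matrix at 0.19, oxidative stress and NRF2 targets at -0.11, and fatty acid oxidation and PPAR alpha targets at -0.10. The lipogenesis call was lost without obese replicate 2 (0.140), the fatty acid oxidation call without lean replicate 2 (0.218) and the stellate call without lean replicate 3 (0.0502), obese replicate 2 (0.159) and obese replicate 4 (0.0625) (camera adjusted p in parentheses). The oxidative stress call was lost without lean replicate 3 (0.0954), obese replicate 1 (0.0725) and obese replicate 3 (0.0605), and the extracellular matrix call without lean replicate 2 (0.102), lean replicate 3 (0.0581), lean replicate 4 (0.0510), obese replicate 1 (0.0619), obese replicate 2 (0.227) and obese replicate 4 (0.0556). The erythroid call held without any 1 array, with a median of -0.84 without obese replicate 2. Across 20 other settings the erythroid median came as near 0 as -0.11. Every list call was lost with an estimated correlation. For 3 genes all 4 lean arrays moved one way and all 4 obese arrays the other, with differences of 0.84 for Afp (adjusted p = 0.310), -0.45 for Cyp2c11 (0.615) and -0.57 for Or4f7c (0.509), none of which passed.

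The lean calls were weighed first, since every array carried TU in Cy5 and a dye bias of a probe shared by both slides would give its genes an obese over lean log2 ratio near 1. Over the 48 features called in lean rats the median ratio was 0.291. Its 95% bootstrap interval, 0.191 to 0.418, resampled features and not arrays, and features are not independent replicates. For a second measure, the 48 features of largest absolute t were picked anew with 2 lean arrays. The sum of their obese responses over that of the other 2 lean arrays, each taken in the picked direction, was 0.149 to 0.429. The first measure is pulled below 1 because its features were picked for a large lean ratio, which the second avoids. On the other 2 lean arrays the lean response was 0.276 to 0.783 of that on the arrays used to pick. The second measure argues against such a bias as the whole cause. A bias of single probes was also looked at in the called lean genes with another probe. The brightest other probe shared the lean direction in 4 of 6 genes (66.7%). It gave a median of 0.471 of the reported log2 ratio. So few genes cannot decide, and no conclusion is drawn from them. For the 3 calls shared by both genotypes, 1 gene (Ugt2b) had other probes that all shared the direction in both, so for that group a dye bias and an effect of TU cannot be told apart. The gene lists were not weighed in this way. Array medians averaged -0.17 in lean and -0.19 in obese rats for Kupffer markers, and 0.16 and 0.16 for male-biased genes. A dye bias shared by both slides would give such alike values too. With the signs of the 4 arrays turned, 1 of 8 assignments gave as many lean calls (48, against at most 0 in any other). For obese calls it was 1 of 8 as well (3, against at most 0). These are too few assignments to exclude chance. A dye effect of the lean slide alone and a response that depends on leptin signalling, which the design names as a biological cause, both stay open as untested.

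The spread between arrays in the lipogenesis and fatty acid oxidation responses was weighed next, with array medians of lipogenesis of -0.34, -0.31, -0.080 and -0.13 in lean and -0.54, -1.40, -0.046 and -0.12 in obese rats, and of fatty acid oxidation of 0.25, 0.35, 0.10 and 0.10 and 0.071, 0.082, 0.015 and 0.077. A difference in clock phase between the animals of an array was tested over 8 arrays by setting a clock gene score against the fatty acid oxidation minus the lipogenesis median (Pearson r = 0.452, exact permutation p = 0.271, adjusted 0.542 over 2 relations, Spearman rho = 0.286, permutation p = 0.501, adjusted 0.703, 95% interval of r -0.371 to 0.877), and r was -0.540 without the 2 farthest arrays. A difference in feeding state, by a score of fasting over feeding genes set against the same value, gave r = 0.0467 (exact permutation p = 0.903, adjusted 0.903, rho = 0.167, permutation p = 0.703, adjusted 0.703, 95% interval -0.680 to 0.727), and r was -0.320 without the 2 farthest. Within lean rats the feeding score was above 0 on all 4 arrays (2.70, 3.36, 0.961 and 0.587 log2 units) with r = 0.978 (rho = 0.8, exact permutation p = 0.125 and 0.333) and r was -0.980 for the clock (rho = -0.6, p = 0.292 and 0.417), while within obese rats they were -0.146 (scores 0.355, -0.142, -0.545 and 0.869, rho = 0.2, p = 0.792 and 0.917) and 0.747 (rho = 1, p = 0.292 and 0.0833), with no adjusted p under 0.333 over 4 relations. The arrays are too few to decide, so either explanation could hold in part, in lean rats too, and a varying effect of TU between animals stays open as untested.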

How the results depend on the processing

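No alternative was added after the data were seen, and no test in this part was chosen only after the result was seen. The main counts of features past the threshold were 48 (31 higher, 17 lower) for the lean response, 3 for the obese response, 1 for the difference, 3423 under vehicle and 4755 under TU, and the covariance of the vehicle difference with the obese response was -0.0151. No filter, the stricter filter and every probe on its own kept these 5 counts within 1.5 times, with 40 to 48 lean, 3 obese and 1 difference calls, as did quantile normalization (4146 and 4945) and the separate-channel model (4846 and 4956) for the last 2. Beside the settings given next, r across genes was 0.340 to 0.430. Without background correction the counts were 335 lean, 81 obese and 0 for the difference (limma, 2330 at an unadjusted p under 0.05), with a covariance of -0.0253. With the scanner software's processed signals they were 249 (136 higher, 113 lower), 218 (161 higher, 57 lower), 5411 under vehicle and 7320 under TU, with a covariance of -0.0642. The authors' log ratios gave 250 lean (137 higher, 113 lower) and 201 obese (148 higher, 53 lower). Median centring without loess gave 5484 lean (269 higher, 5215 lower), 0 obese and 0 for the difference (1216 and 8109 unadjusted). It turned the r across genes to -0.117, Hsd17b13 in lean rats to -0.074 and the lean median of steroid hormone genes to -0.36, and for lean triglyceride export, whose median went from -0.024 to -0.34, it turned the direction of the camera test. It also turned the difference medians of fatty acid oxidation to 0.52, the mitochondrial respiratory chain to 0.82, oxidative stress to 0.44 and triglyceride export to 0.73, while the median of all genes moved to -0.21 in lean rats and 0.22 for the difference. Ratios scaled between arrays gave 0 lean, 0 obese and 0 for the difference (3174, 2996 and 1769 unadjusted), and an extracellular matrix difference of -0.044. With trend and robust settings the counts were again 0, 0 and 0 (3143, 2499 and 1909 unadjusted). The mean of a gene's probes gave 0 obese and 0 for the difference (2893 and 1767 unadjusted). Array weights gave 856 lean (294 higher, 562 lower), 181 obese, 21 for the difference, 5747 and 8305. At least 1.5-fold were 31 lean, 1557 vehicle and 1892 TU features, by construction fewer. With the genotype's own arrays there were 261 lean (87 higher, 174 lower) and 0 obese (1544 unadjusted) calls. The stricter filter, which left 17423 probes, put Pcna under vehicle at 0.39 by a different probe. With the number as a replicate block the counts were 21 lean (12 shared), 0 obese and 0 for the difference (3139 and 1724 unadjusted) and 1441 under vehicle. The block ended the list calls for drug metabolism and triglyceride export (lean), steroid hormones (obese), extracellular matrix (difference), and adipocyte and cell cycle (TU). It added erythroid and female-biased (lean), ER stress, fatty acid oxidation, female- and male-biased (obese), acute phase and hepatocyte (difference) and erythroid (vehicle). The log2 ratios of same-numbered lean and obese arrays correlated with r of 0.259, 0.103, 0.237 and 0.319, where all 16 lean and obese pairs gave 0.103 to 0.437. A separate check of pairing, a different measure, gave r of 0.0558, -0.104, 0.156 and -0.00733. In it 2 of 4 lean arrays correlated best with their own number. Same-numbered arrays also had the same position on their slides, and so few arrays cannot decide whether they were matched. With single arrays left out the counts were 1 to 1047 lean, 0 to 3 obese, 0 to 3 for the difference, 1465 to 4743 under vehicle and 3009 to 7282 under TU, with r across genes of 0.289 to 0.463 and a covariance of -0.0233 to -0.00603. Pck1 under vehicle, -0.29 with all arrays, ranged from -0.84 without obese replicate 3 to 1.04 without obese replicate 1. Across all settings, list calls kept their direction and side of the threshold in 517 of 722 values, with 200 weaker and 5 reversed by the direction of the camera test, and gene calls in 1387 of 1779, with 390 weaker and 2 reversed. Medians also crossed 0 with median centring where the test did not turn, in lean rats for fatty acid oxidation (-0.23), male-biased genes (-0.30), acute phase (-0.20), drug metabolism (-0.23) and hepatocytes (-0.13), and for lipogenesis in the difference (0.19). Of values not called, 1730 of 1966 for lists and 4532 of 4818 for genes stayed as they were. All 38 list calls were lost with an estimated correlation. The cause of these changes was not tested, except where the construction is named. A block for slide and scan was not run because each genotype lies on its own slide and scan, so both cannot be told apart. Signal over background limits the low end, since 50.3% to 68.9% of probes lay well above background per channel, and a ratio of dim signals depends on the background correction by construction.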

Other observations

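The tests of single-probe slide effects and of slides shared by genotypes were chosen only after the result was seen, while the tests that regroup the arrays were written before. Some hormone signalling and acute phase genes differed between obese and lean livers under vehicle, although their lists were not called (camera adjusted p = 0.797 and 0.671). The growth hormone receptor Ghr was higher in obese rats (0.82 ± 0.079, adjusted p = 0.00125, where 2 other probes gave 0.82 and -0.22), while the feedback inhibitor Cish (-1.07 ± 0.18, adjusted p = 0.00883) and the insulin-suppressed Igfbp1 (-1.19 ± 0.22, adjusted p = 0.0129) were lower. The mean of its probes put Ghr at 0.47. The endotoxin-binding protein Lbp was lower (-2.39 ± 0.18, adjusted p = 0.000504), as was A2m (-1.51 ± 0.25, adjusted p = 0.00956), and Orm1 (0.99 ± 0.11) and Icam1 (0.91 ± 0.17) were higher. Of the steroid enzymes, Hsd11b1, which regenerates glucocorticoids, was lower (-1.59 ± 0.12, adjusted p = 0.000476), as was Srd5a2 (-0.65 ± 0.10, or -1.46 from the scanner software's processed signals), while Cyp17a1 and Srd5a1 were higher, as given above. These genes stayed past the threshold without any 1 array.

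The genotype difference under vehicle was weighed against the slides, since 0 slides held both genotypes and a difference between the slides in RNA handling, labelling or scan cannot be told apart from genotype. If effects of slide or printing on single probes were the whole cause, the brightest other probe would share a gene's direction no more often than chance. It shared the direction in 74.7% (310 of 415, 95% interval 70.3% to 78.6%), which argues against them as the whole cause. The interval treats genes as independent, which they are not. This probe gave a median of 0.342 of the reported log2 difference, so such effects on a part of the calls, or on their size, stay open. Under TU the other probe shared the direction in 77.5% (457 of 590). Only the true split of the 8 arrays gave as many genes under vehicle (1 of 35, real 3423, highest other 0) and under TU (1 of 35, 4755 and 0). This argues against chance for these counts, although 1 of 35 is the smallest share that these splits can reach. Every other split mixed genotypes and slides, which by construction widens the spread within its groups, and the test cannot exclude the slides. For the difference of responses (1 of 35, 1 and 0) a single feature decides and is lost without some arrays, so chance stays open there. The fa/fa genotype and the obese, diabetic state that goes with it stay open as untested biological causes.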
